A study of Mus musculus with 15 samples.

How the data were processed

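RNA was measured in bulk pancreatic islets of 9 to 10 week old FVB/NJ mice, in 15 libraries of 5 groups with 3 libraries each. The groups were wild-type mice (WT), mice with a human IAPP transgene (hIAPP), mice with a rodent IAPP transgene (rIAPP), mice with a human CAST transgene (hCAST), and mice with both human transgenes (hIAPP-hCAST). Per the labels, the transgenes were under an insulin promoter. IAPP is islet amyloid polypeptide, a hormone co-secreted with insulin. The human form can aggregate into amyloid and the rodent form does not. CAST encodes calpastatin, an inhibitor of the calpain proteases. Per the labels, total RNA was isolated with the RNeasy Mini Kit, its integrity was assessed on a Bioanalyzer, and libraries were made with TruSeq with Ribo-Zero and NuGEN Ovation. Libraries are named here by group and replicate number. The numbers 1, 2 and 3 follow accession order and were not used to pair libraries. The numbers in the titles are not shared between groups, and a pairing by litter or handling is neither stated nor excluded. The title numbers of WT and hCAST lie in the same range, those of hIAPP and hIAPP-hCAST in another, and those of rIAPP apart. Only hCAST against WT and hIAPP-hCAST against hIAPP stay within a range. In the other pairwise comparisons, whatever the ranges stand for cannot be separated from the IAPP transgenes. Line, litter and colony were not given in the sources used here and cannot be separated from the group.

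The deposited count table holds whole-number read counts per gene symbol in 24060 entries, of which 2 repeat a symbol, and the values are raw counts from the submitters. The submitters' processing notes name STAR and HTSeq, without versions, and the genome builds GRCm38 and mm10, which are names of the same assembly. The annotation, the strand setting of the counting and the treatment of reads with several matches were not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore uncertain. The deposited FPKM table was used only as an alternative. From the ratio of both tables, its FPKM scaled as the count divided by a gene length and by the column total, in which the reads on ribosomal RNA genes were included. Each of the 15 columns in both tables was matched to a library by its title, and 0 columns were left unused. Human transgene reads were not analysed here, and the mouse Iapp and Cast counts do not measure them as such. Reads of the rodent IAPP transgene may be counted on mouse Iapp, which was not tested. Mitochondrially encoded genes were not analysed here.

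Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default filter on low counts by group, robust dispersions and 1 coefficient per group over all 15 libraries. Of the entries, 15460 passed the filter, and the common biological coefficient of variation was 0.132. Adjusted p is Benjamini-Hochberg over all tested genes within a comparison, and a gene was called changed at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM are TMM-scaled counts relative to library size, given as mean ± SD over n = 3 libraries per group. The 6 pairwise comparisons and an interaction, 7 contrasts in all, were fitted. The interaction is the human IAPP difference on the hCAST background minus that on the WT background. Before the data were examined, the tests, the rule for naming genes, the alternatives to try and 29 gene lists of cell types and pathways were fixed. Of the lists, 27 had at least 3 tested genes, and those described were picked from the 27 after their results were known. A list was tested with camera in limma 3.58.1 with a preset correlation of 0.01, then again with an estimated correlation, both adjusted over the 27 lists within a comparison. Members were also counted as changed when adjusted over the list alone. The preset correlation called 13, 10, 7, 5, 13, 8 and 13 lists in the 7 contrasts in the order described, and the estimated correlation called 0, 0, 1, 0, 0, 2 and 0.

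Named genes were chosen by rule. Iapp, Cast, Ins1, Ins2, Gcg, Sst and Ppy were always eligible. The rule added the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 1 and no overlap between the replicates of the compared groups, a property that chance gives to 10% of genes with 3 libraries against 3. Symbols of predicted genes, pseudogenes and immune receptor segments were left out. It further added up to 4 members with the smallest p of each list described and, where fewer than 3 genes passed, the 3 with the smallest p as not passing. Outside the rule, 1700006A11Rik, H2-Ea-ps, Osbpl1a in the rIAPP comparison, and the neighbours of Sema5a were named after their values were seen. For a gene with 0 counts in a group, a lower bound of the fold was computed against a floor of 3 counts over that group, and the lower limit of the exact 95% interval, which lies below it, is given beside it. For 1 to 3 counts, the ratio is given with an exact 95% binomial interval. These bounds cover counting error only, since reads without molecular identifiers are not independent molecules. The rule and these additions gave 244 gene results besides 1 that is not reported here, of which the text names a part, chosen after their values and stability were seen, and the stability counts cover all 244. Coordinates are from the GENCODE vM21 annotation of GRCm38.

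The tests were checked on simulated counts for 15386 genes drawn from the means, dispersions and library sizes, with 200 genes changed. The changed genes were drawn from those with a mean CPM of at least 1, so recovery at lower counts was not checked. All libraries shared 1 dispersion per gene, which does not model extra spread in WT. Of the genes changed 1.5-, 2- and 4-fold, 61.2%, 85.1% and 97.0% were recovered in the hIAPP and WT comparison, where 8 of 170 calls were false. In the hIAPP-hCAST and hCAST comparison, 71.6%, 88.1% and 97.0% were recovered, with 10 of 181 calls false. The comparison of hCAST with WT, simulated without change, gave 0 calls. One list planted as changed reached an adjusted p of 8.21e-25 by camera with the preset correlation, and 0 other lists were called. The simulated genes were drawn independently of each other. The check therefore does not cover lists whose members are correlated.

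Library totals lay between 28287011 and 40191501 counts. After the tables were opened, 3 libraries, WT 2, WT 3 and rIAPP 2, were found to hold most of their counts on the 3 genes Rn45s, Lars2 and Mir6236, which collect ribosomal RNA reads. Alternatives planned beforehand were DESeq2 size factors, TMM without hormone and acinar genes, DESeq2 1.42.0, no filter on low counts, only the compared groups, the mean of acinar markers as a covariate, limma on log2 of FPKM plus 1 or plus 0.1, and leaving out each replicate of the compared groups in turn, which leaves that group with 2 libraries. Chosen after seeing the data were leaving out those 3 libraries, leaving out those 3 genes, using the hCAST libraries in place of WT, limma voom with sample quality weights, an overlap with no shared library, and leaving out each replicate of the groups not compared. Leaving out the 3 libraries leaves WT with 1 library, which is then assumed to vary like the other groups. No pair of libraries of a group matched within sampling noise, as the lowest chi-square per gene was 11.0. The labels do not state that replicates are separate animals beyond the numbers in their titles, so p-values measure the spread between these samples, which may be technical.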

Results

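Islet RNA was sequenced in 15 libraries, 3 each from WT, hIAPP, rIAPP, hCAST and hIAPP-hCAST mice. The depth in counts was 37989787, 29135153 and 28287011 in WT 1, 2 and 3, 36293817, 36763315 and 35510664 in hIAPP, 35780458, 29438284 and 34250995 in rIAPP, 34904705, 37829688 and 37706974 in hCAST, and 36295060, 37916324 and 40191501 in hIAPP-hCAST. Insulin genes (Ins1 and Ins2) held 15.8%, 16.3% and 16.1% of the counts outside the ribosomal-rich genes in WT, 11.8%, 9.90% and 10.7% in hIAPP, 7.06%, 5.34% and 7.18% in rIAPP, 14.1%, 14% and 12.2% in hCAST, and 11.6%, 8.92% and 12% in hIAPP-hCAST. Genes of acinar cells, the enzyme-secreting cells around islets, held 8.25%, 4.63% and 1.97% in WT, 8.47%, 15.5% and 7.92% in hIAPP, 12.3%, 16.4% and 12.9% in rIAPP, 5.32%, 5.79% and 11% in hCAST, and 8.18%, 16% and 1.29% in hIAPP-hCAST. The ribosomal-rich genes Rn45s, Lars2 and Mir6236 held 9.40%, 94.3% and 68.9% of all counts in WT 1, 2 and 3, 1.99%, 67.7% and 11.8% in rIAPP, and 1.28%, 7.63% and 0.351% in hIAPP. WT 2, WT 3 and rIAPP 2 thereby kept 1667190, 8796210 and 9510502 other counts, against 30199765 to 40062153 in the other libraries. Across genes, which are not independent replicates, the correlation between libraries of a group was lowest in WT, at 0.941 to 0.983. Because FPKM was divided by totals that include ribosomal reads, log2 of FPKM plus 1 moved the median of all genes by 1.26 between hIAPP and WT, 0.80 between rIAPP and WT, 1.26 between hCAST and WT, and 0.40 between hIAPP and rIAPP.

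**Figure D1:**
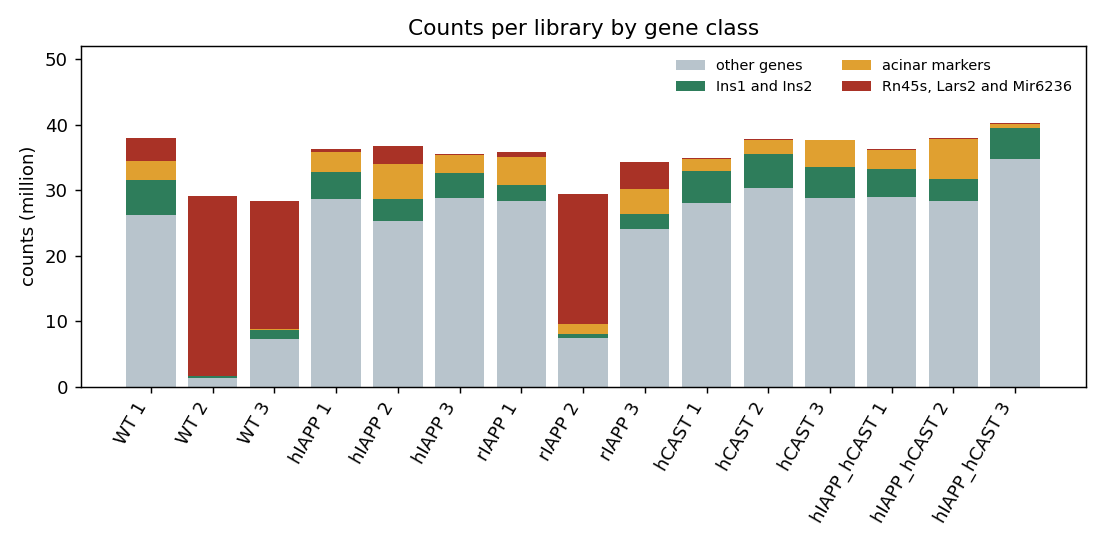
Counts per library, stacked by other genes, Ins1 and Ins2, acinar markers, and the 3 ribosomal-rich genes Rn45s, Lars2 and Mir6236. The ribosomal-rich genes hold 94.3% of counts in WT 2, 68.9% in WT 3 and 67.7% in rIAPP 2.

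The comparison of hIAPP with WT asked how a human IAPP transgene in beta cells changes islet gene expression. Macrophage genes rose in hIAPP islets: of 22 tested markers, 19 rose, 0 fell and 3 did not pass, and 21 rose when adjusted over the list alone. The median log2 fold change of the list was 1.62 (camera adjusted p = 1.13e-18; adjusted p = 0.177 with an estimated correlation). Lyz2, a lysozyme of myeloid cells, had 157 ± 24.7 CPM in hIAPP and 9.53 ± 1.28 in WT (SD, n = 3; log2 fold change 4.0 ± 0.312 SE, adjusted p = 3.72e-05). Gpnmb, a glycoprotein of lipid-laden and lysosome-rich macrophages, rose by 4.65 ± 0.550 on the log2 scale, Cx3cr1, the fractalkine receptor, by 2.41 ± 0.258, and C1qb, a complement subunit, by 1.59 ± 0.185. The size of the Gpnmb fold rests on low WT values, at 0.344, 1.31 and 0.848 CPM in WT 1, 2 and 3. In hIAPP 1, 2 and 3 it had 10.5, 18.2 and 11.3. Atp6v0d2, a proton pump subunit, had 359 counts over the hIAPP libraries and 3 over WT, a ratio of 48.2 with a counting interval of 16.3 to 235. Matrix and stellate cell genes rose as well, 19 of 22 with 0 falling, and 21 when adjusted over the list alone (median 1.31, camera adjusted p = 1.21e-12; adjusted p = 0.189 with an estimated correlation). Fn1, which encodes fibronectin, had 15.5 ± 1.52 CPM against 2.11 ± 0.951, and Pdgfrb, a receptor of pericytes and stellate cells, rose by 1.31 ± 0.155. Acinar share in these libraries was 7.92% to 15.5% in hIAPP and 1.97% to 8.25% in WT, and 0 of 22 acinar markers passed (median 1.07, camera adjusted p = 0.00341; adjusted p = 0.596 with an estimated correlation). Without WT 3 that list had a median of 0.67 and an adjusted p of 0.209.

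Beta-cell identity genes fell in hIAPP islets, 15 of 30 with 0 rising and 15 not passing, and 19 fell when adjusted over the list alone (median -0.43, camera adjusted p = 2.33e-10; adjusted p = 0.177 with an estimated correlation). Ucn3, a peptide of mature beta cells, had 237 ± 24.3 CPM against 456 ± 26.5 in WT (log2 fold change -0.94 ± 0.127, adjusted p = 0.000377), and Ero1lb, an oxidase for proinsulin folding, fell by 0.82 ± 0.151. Ins2 fell by 0.71 ± 0.113 (adjusted p = 0.00103) and Ins1 by 0.54 ± 0.135 (adjusted p = 0.0173). Ins1 no longer passed without hIAPP 2 (-0.51, adjusted p = 0.0658) or without hIAPP 3 (-0.51, adjusted p = 0.0627), and against hCAST in place of WT neither Ins1 (-0.36) nor Ins2 (-0.33) passed. Nnat, a membrane proteolipid of endocrine cells, had 37.3 ± 6.25 CPM against 120 ± 6.22, and Trpm5, a cation channel, 49.4 ± 18.6 against 158 ± 17.6. Genes linked to dedifferentiation rose in 4 of 12 with 0 falling and 8 not passing, and 4 rose and 1 fell when adjusted over the list alone (median 0.43, camera adjusted p = 0.0110; adjusted p = 0.177 with an estimated correlation). Among them Vgf, a secreted neuroendocrine protein, rose by 1.04 ± 0.127, and Aldh1a3, a retinal dehydrogenase, had 63.5 ± 19.8 CPM against 7.55 ± 5.21 (adjusted p = 0.00352), which did not pass without the 3 ribosomal-rich libraries (0.0506). The mean log2 CPM of the dedifferentiation list exceeded WT by 0.77 ± 0.128 SE in hIAPP, 0.88 ± 0.128 in rIAPP and 0.36 ± 0.128 in hCAST. Between hIAPP and rIAPP it differed by -0.11 ± 0.128, so the rise of the list mean was not particular to human IAPP. Single members did differ, with Vgf higher and Neurog3 lower in hIAPP than in rIAPP. Iapp (adjusted p = 0.170), Cast (0.616), Gcg (0.570), Sst (0.227) and Ppy (0.821) did not pass.

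Sema5a, a semaphorin for axon guidance, had the smallest adjusted p of the comparison, at 532 ± 5.61 CPM in hIAPP and 13.4 ± 3.23 in WT (log2 fold change 5.44 ± 0.145, adjusted p = 2.56e-13). It lies on chromosome 15 of GRCm38 from 32244810 to 32696341, 147 bases from the lincRNA Snhg18 (32240565 to 32244662), which rose by 4.07 ± 0.129. Osbpl1a, an oxysterol-binding protein gene on chromosome 18 (12755314 to 12941841), rose by 2.96 ± 0.146. In all, 969 genes were higher and 864 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 33.1% of the tested genes had no overlap between the groups, where chance gives 10%. The count of 1833 was 1003 without hIAPP 2, 1006 without hIAPP 3, 995 without WT 3, 1197 without hIAPP 1, and 383 without the 3 ribosomal-rich libraries, a choice made after seeing the data. On log2 of FPKM plus 1 the split was 12555 higher and 4 lower. Of 52 called genes chosen for naming, 14 lost the call when at least 1 replicate of either group was left out and 23 without those 3 libraries.

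**Figure D2:**
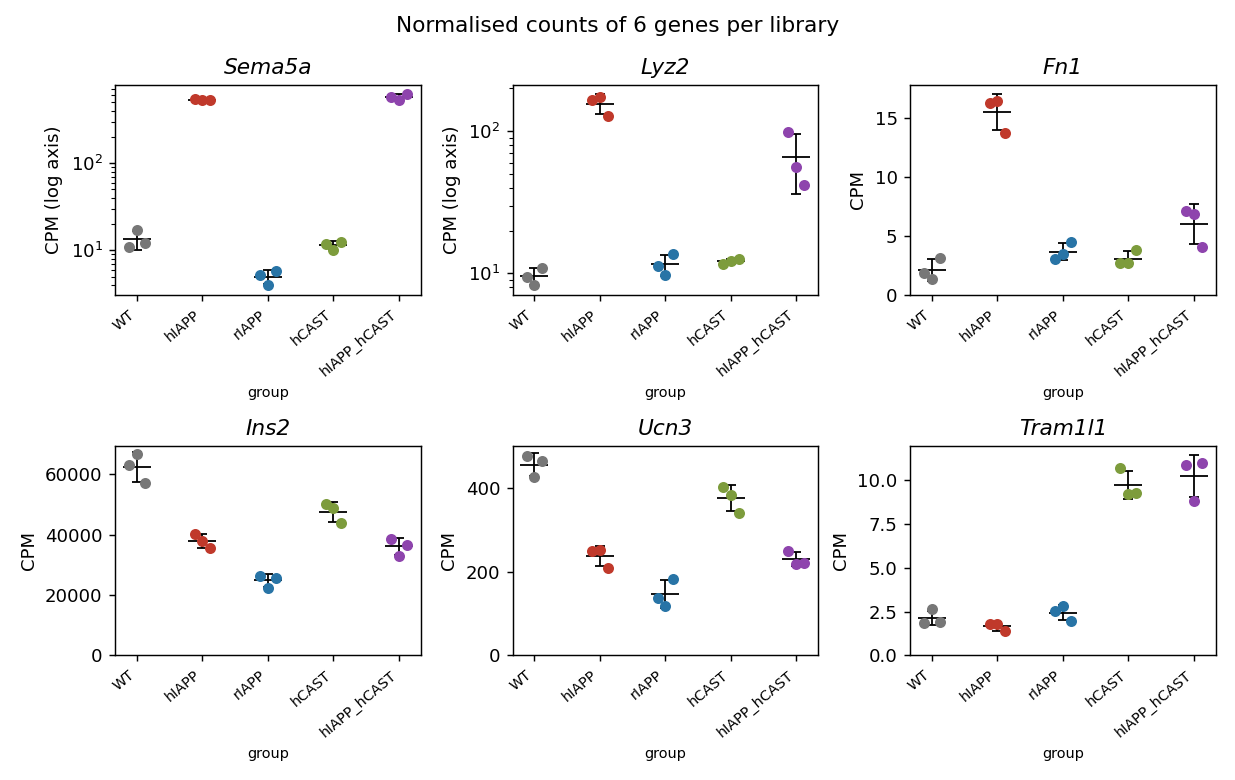
CPM of Sema5a and Lyz2 (log axis), Fn1, Ins2, Ucn3 and Tram1l1 per library in the 5 groups, with bars for mean ± SD (n = 3). Sema5a is near 532 CPM in hIAPP and 570 in hIAPP-hCAST against 13.4 in WT, and Lyz2 is 157 in hIAPP against 9.53 in WT.

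The comparison of rIAPP with WT asked what a rodent IAPP transgene, the form that does not aggregate, changes by itself. Beta-cell identity genes fell in 26 of 30 with 0 rising and 4 not passing, and 27 fell when adjusted over the list alone (median -1.19, camera adjusted p = 4.03e-18; adjusted p = 0.140 with an estimated correlation). Pcsk1, a prohormone convertase, had 109 ± 9.46 CPM in rIAPP and 459 ± 78.1 in WT (SD, n = 3; log2 fold change -2.08 ± 0.127, adjusted p = 1.41e-08), Ucn3 146 ± 32.7 against 456 ± 26.5, and Ins2 fell by 1.33 ± 0.114 and Ins1 by 1.44 ± 0.137. Granule genes Scg2 and Pcsk2 fell by 1.03 ± 0.102 and 0.87 ± 0.0859, within a list of 20 in which 8 fell, 1 rose and 11 did not pass, and the same counts held when adjusted over the list alone (median -0.18, camera adjusted p = 0.00131; adjusted p = 0.486 with an estimated correlation). Neurog3, the endocrine progenitor factor, had 14 ± 3.0 CPM against 1.93 ± 0.423 (adjusted p = 3.82e-07), and Gc, a vitamin D carrier of alpha cells, 387 ± 34.6 against 64.6 ± 9.34. Thsd7b, Cdh10, a cadherin, and Gabra3, a GABA receptor subunit, had ratios of 237 (counting interval 42.4 to 9396), 122 (21.7 to 4852) and 103 (35.2 to 503), and Lrp1b was at least 36.1-fold higher, against a floor of 3 counts over WT (lower limit of the counting interval 29.1). Col8a2, a collagen, rose by 6.87 ± 0.552. Endothelial genes rose in 10 of 13, with 0 falling and 3 not passing, and 12 rose when adjusted over the list alone, among them Eng (0.71 ± 0.124) and Plvap (0.53 ± 0.0926) (median 0.53, camera adjusted p = 8.19e-05; adjusted p = 0.486 with an estimated correlation).

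Macrophage genes in rIAPP islets gave 0 rising, 2 falling and 20 not passing, with the same counts adjusted over the list alone (median -0.02, mean 0.07, camera adjusted p = 0.830). Matrix genes gave 13 rising, 1 falling and 8 not passing, with 15 rising and 1 falling when adjusted over the list alone (median 0.81, camera adjusted p = 6.42e-05; adjusted p = 0.524 with an estimated correlation), with Col1a2, a fibrillar collagen chain, at 1.94 ± 0.373 and Loxl2, a collagen cross-linker, at -0.83 ± 0.131. Acinar share was 12.3% to 16.4% in rIAPP and 1.97% to 8.25% in WT, and 1 of 22 acinar markers rose (median 1.38, camera adjusted p = 0.000495; adjusted p = 0.613 with an estimated correlation). Without the 3 ribosomal-rich libraries that camera adjusted p was 0.259. Osbpl1a, named outside the rule, had 26.9 ± 1.15 CPM against 2.99 ± 0.697 in WT. Mouse Iapp did not pass (adjusted p = 0.240) and passed without WT 2 (log2 fold change 0.66, adjusted p = 0.000147), and Cast (0.0577) and Ppy (0.580) did not pass. Gcg, glucagon, did not pass (0.0522) and passed without rIAPP 3 (0.0281) or WT 1 (0.0336). Sst, somatostatin, fell by 0.30 (adjusted p = 0.0440), which did not pass without rIAPP 1 (0.103), rIAPP 2 (0.124), rIAPP 3 (0.0639), WT 2 (0.112) or WT 3 (0.121). In all, 1650 genes were higher and 1949 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 1525 were called without the 3 ribosomal-rich libraries, with 820 on log2 of FPKM plus 1, split into 817 higher and 3 lower. Genes called in both comparisons with WT in the same direction numbered 1134, against 212 for independent lists, and 13 were opposite. Draws with no effect in either group, which share the WT libraries, called at most 1 gene per comparison. Their overlap of at most 1 therefore cannot show how much of the 1134 comes from sharing. The covariance of the log2 fold changes was 0.238 against a median of 0.0744 (0.0680 to 0.0864) in those draws. Their correlation over genes, which are not independent replicates, was 0.630 against 0.654 (0.626 to 0.691) in the draws. The draws do not model the extra spread of the WT libraries. Part of the excess over 212 may come from the shared WT libraries. With rIAPP set against hCAST, which shares no library with hIAPP and WT, 804 were called in the same direction, against 204 for independent lists, and 41 opposite, with a correlation of 0.335. The overlap was 612 without hIAPP 3, 629 without hIAPP 2, 627 without WT 3 and 210 without the 3 ribosomal-rich libraries.

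**Figure D3:**
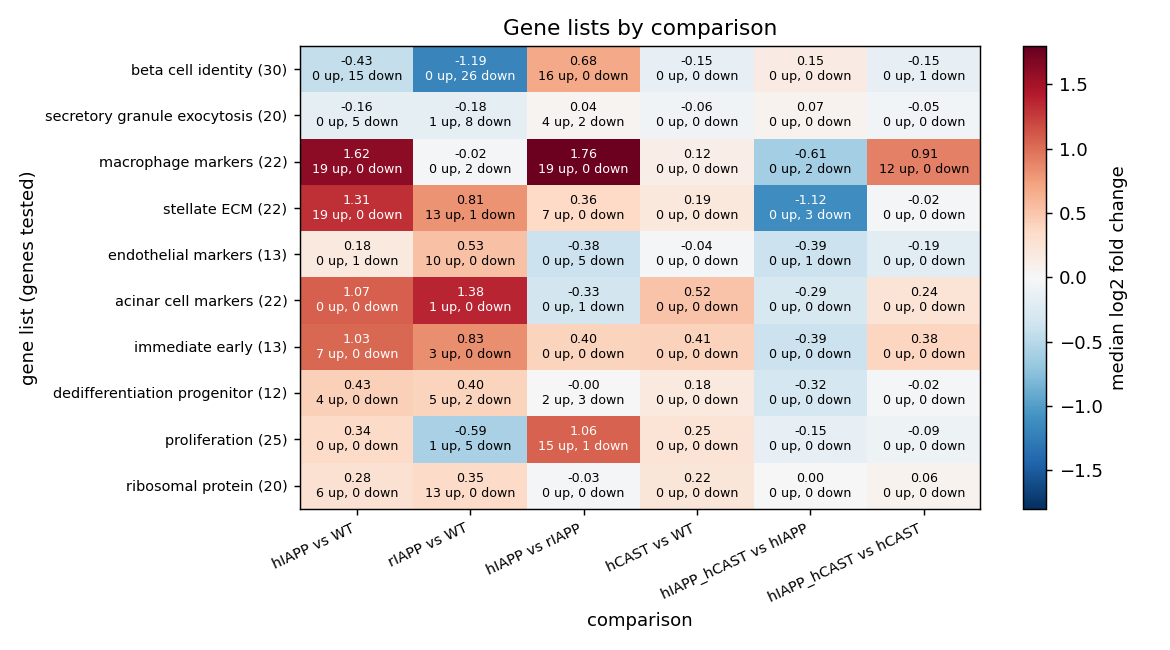
Median log2 fold change of 10 gene lists in the 6 pairwise comparisons, with the numbers of members called higher and lower. Beta-cell identity genes have a median of -0.43 in hIAPP and -1.19 in rIAPP against WT, and macrophage genes 1.62 and -0.02.

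The comparison of hIAPP with rIAPP set the aggregating against the non-aggregating form. Macrophage genes were higher in hIAPP in 19 of 22, with 0 lower and 3 not passing, and 20 higher when adjusted over the list alone (median 1.76, camera adjusted p = 7.37e-21; adjusted p = 0.0830 with an estimated correlation). Lyz2 had 157 ± 24.7 CPM in hIAPP and 11.5 ± 1.97 in rIAPP (SD, n = 3; log2 fold change 3.74 ± 0.281, adjusted p = 3.54e-06), and Ms4a7, a macrophage surface protein, was higher by 2.26 ± 0.173. The mean log2 CPM was higher in hIAPP by 1.75 ± 0.250 SE for macrophage, 0.74 ± 0.204 for lymphocyte and 0.36 ± 0.250 for matrix genes. Lysosome, autophagy and proteasome genes gave 5 higher of 23, 0 lower and 18 not passing, and 5 higher when adjusted over the list alone (median 0.19, camera adjusted p = 0.000121; adjusted p = 0.0233 with an estimated correlation), with Ctsb and Ctsd, lysosomal proteases, at 0.79 ± 0.0945 and 0.78 ± 0.113. Beta-cell identity genes were higher in hIAPP in 16 of 30, with 0 lower and 14 not passing, and 20 higher when adjusted over the list alone (median 0.68, camera adjusted p = 1.23e-12; adjusted p = 0.135 with an estimated correlation). Pcsk1 was higher by 1.5 ± 0.124, Abcc8, the sulfonylurea receptor, by 1.21 ± 0.147, and Ins1 by 0.90 ± 0.135. Vgf was higher by 2.61 ± 0.129 and Neurog3 lower, at -2.33 ± 0.190. Cell-cycle genes were higher in 15 of 25, 1 was lower and 9 did not pass, with 16 higher and 1 lower when adjusted over the list alone (median 1.06, camera adjusted p = 3.77e-05; adjusted p = 0.391 with an estimated correlation), with Cdk1, a mitotic kinase, at 1.84 ± 0.299. Against WT, 0 of 25 cell-cycle genes passed in hIAPP in either count (median 0.34, camera adjusted p = 0.296, and 0.00734 without WT 2). In rIAPP against WT, 1 rose, 5 fell and 19 did not pass, with the same counts adjusted over the list alone (median -0.59, camera adjusted p = 0.0106; adjusted p = 0.524 with an estimated correlation), and the camera adjusted p was 0.0877 without WT 2. Endothelial genes were lower in hIAPP than in rIAPP in 5 of 13, 0 were higher and 8 did not pass, and 8 were lower when adjusted over the list alone (median -0.38, camera adjusted p = 3.77e-05; adjusted p = 0.440 with an estimated correlation), with Eng at -0.53 ± 0.114 and Emcn, an endothelial sialomucin, at -0.48 ± 0.101. Sema5a had 532 ± 5.61 against 4.98 ± 0.908 CPM, and Thsd7b had 1 count over hIAPP and 427 over rIAPP. Mouse Iapp was lower in hIAPP at -0.67 ± 0.174 (adjusted p = 0.0158), which no longer passed without hIAPP 1 (adjusted p = 0.0571) or rIAPP 2 (0.0603). Iapp passed against WT in neither hIAPP nor rIAPP, so this difference is not shown to be a fall in hIAPP. Reads of the rodent transgene may raise the Iapp counts of rIAPP, which was not tested. Ins2 was higher by 0.61 ± 0.112 (adjusted p = 0.00120), and with only the compared groups neither Iapp (0.0694) nor Ins2 (0.123) passed. Cast (0.258), Gcg (0.281), Sst (0.607) and Ppy (0.866) did not pass. The calls were 1192 higher and 817 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), 1317 in all without hIAPP 1, 1302 without rIAPP 2 and 1332 without rIAPP 1. On log2 of FPKM plus 1 the split was 241 and 75, and voom with sample weights, chosen after seeing the data, gave 3476.

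The comparison of hCAST with WT asked what human calpastatin changes without human IAPP. In hCAST, 3 genes were higher and 0 lower (edgeR quasi-likelihood test, Benjamini-Hochberg). Tram1l1, a translocon-associated membrane protein gene, had 9.74 ± 0.821 CPM in hCAST and 2.14 ± 0.421 in WT (SD, n = 3; log2 fold change 2.32 ± 0.182, adjusted p = 8.29e-06). The other passing genes fall outside the rule and were named after their values were seen. H2-Ea-ps, a major histocompatibility pseudogene, had 49.4 ± 2.60 CPM against 0.484 ± 0.0518 (adjusted p = 0.000236), and without the 3 ribosomal-rich libraries its adjusted p was 0.130, the highest over its alternatives, which began at 6.53e-22. The gene 1700006A11Rik was at least 29.5-fold higher (225 counts over hCAST against 0 over WT, floor of 3 counts over the group, lower limit of the counting interval 23.8, adjusted p = 0.00219), and its adjusted p was 0.0952 without WT 1. Tram1l1 lies on chromosome 3 from 124320855 to 124324743 and 1700006A11Rik from 124400989 to 124426040. H2-Ea-ps, annotated as a polymorphic pseudogene, lies on chromosome 17 from 34341959 to 34344645. Iapp (0.701), Cast (1.0), Ins1 (0.844), Ins2 (0.560), Gcg (0.821) and Sst (0.822) did not pass, and the next genes by p were Rps16 at 0.42 (adjusted p = 0.0778) and St5 at -0.43 (0.0778). Ribosomal protein genes gave 0 of 20 passing, with 7 rising when adjusted over the list alone (median 0.22, camera adjusted p = 1.67e-08; adjusted p = 0.771 with an estimated correlation), and without the 3 ribosomal-rich libraries the camera adjusted p was 0.0773. The same list rose against WT in hIAPP in 6 of 20, with 0 falling and 14 not passing, and 13 when adjusted over the list alone (median 0.28, camera adjusted p = 2.23e-06; adjusted p = 0.311 with an estimated correlation). In rIAPP it gave 13 rising, 0 falling and 7 not passing, with 14 rising when adjusted over the list alone (median 0.35, camera adjusted p = 3.98e-06; adjusted p = 0.486 with an estimated correlation). Its mean log2 CPM was 7.36, 6.92 and 7.20 in WT 1, 2 and 3, and 7.35, 7.41 and 7.47 in hCAST. Between hCAST and WT the mean log2 CPM differed by 0.41 ± 0.250 SE for macrophage genes and -0.13 ± 0.0898 for beta-cell identity genes. With an unadjusted p under 0.05 there were 1133 genes, and DESeq2 called 28, 8 higher and 20 lower. On log2 of FPKM plus 1, 13132 were higher and 3 lower.

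The comparison of hIAPP-hCAST with hIAPP asked whether human calpastatin changes expression where human IAPP is present. Matrix genes were lower with hCAST in 3 of 22, 0 were higher and 19 did not pass, and 20 were lower when adjusted over the list alone (median -1.12, camera adjusted p = 7.31e-31; adjusted p = 0.0697 with an estimated correlation). Fn1 had 6.01 ± 1.72 CPM in hIAPP-hCAST and 15.5 ± 1.52 in hIAPP (SD, n = 3; log2 fold change -1.37 ± 0.216, adjusted p = 0.0107), and Loxl1, a collagen cross-linker, 3.44 ± 0.979 against 9.03 ± 0.918 (adjusted p = 0.00125). Macrophage genes were lower in 2 of 22, 0 were higher and 20 did not pass, and 14 were lower when adjusted over the list alone (median -0.61, camera adjusted p = 3.05e-12; adjusted p = 0.182 with an estimated correlation). Lyz2 had 65.6 ± 29.7 CPM against 157 ± 24.7 and did not pass (adjusted p = 0.0543). Without hIAPP-hCAST 1 its adjusted p was 0.000113. Endothelial genes gave 0 higher, 1 lower and 12 not passing, and 10 lower when adjusted over the list alone (median -0.39, camera adjusted p = 9.35e-13; adjusted p = 0.117 with an estimated correlation), with Eng, an endothelial receptor, at -0.76 ± 0.115. Beta-cell genes gave 0 of 30 passing in either count (median 0.15, camera adjusted p = 0.000909; adjusted p = 0.344 with an estimated correlation), and the camera adjusted p was 0.0770 without hIAPP 3. Ins2 had a log2 fold change of -0.07 (adjusted p = 0.878), and Iapp, Cast (0.486), Ins1, Gcg, Sst and Ppy did not pass. The mean log2 CPM of the matrix list was 4.76, 4.68 and 3.77 in hIAPP-hCAST 1, 2 and 3 and 5.61, 5.46 and 5.35 in hIAPP. The acinar share was 1.29% in hIAPP-hCAST 3 and 8.18% and 16% in its other libraries. Acinar markers gave 0 of 22 passing in either count, with 1 above 0 (median -0.29, camera adjusted p = 0.000115; adjusted p = 0.507 with an estimated correlation), and a median of 0.23 without hIAPP-hCAST 3 (adjusted p = 0.337). Duct markers gave 0 of 12 passing in either count, with 1 above 0 (median -0.23, camera adjusted p = 0.00415; adjusted p = 0.298 with an estimated correlation), and a camera adjusted p of 0.282 without hIAPP-hCAST 3. Schwann and glial markers gave 0 of 7 passing, with 2 lower when adjusted over the list alone (median -0.53, camera adjusted p = 0.000909; adjusted p = 0.298 with an estimated correlation). Tram1l1 had 10.3 ± 1.22 CPM against 1.66 ± 0.235 (adjusted p = 8.24e-08), H2-Ea-ps 89.2 ± 33.2 against 0.266 ± 0.280 (adjusted p = 4.00e-06, and 0.0733 with only the compared groups), and 1700006A11Rik was at least 75.2-fold higher with a floor of 3 counts over the group (lower limit of the counting interval 60.7). In all, 14 genes were higher and 58 lower (edgeR quasi-likelihood test, Benjamini-Hochberg). The count of 72 was 2 with only the compared groups, 30 without the 3 ribosomal-rich libraries, 18 without hIAPP 2, 21 without hIAPP 1, 28 without hIAPP 3, 175 without hIAPP-hCAST 2 and 129 without hIAPP-hCAST 1. Fn1 no longer passed without hIAPP 1 (adjusted p = 0.0530) or hIAPP 2 (0.0528), and of 23 called genes chosen for naming 15 lost the call in at least 1 such removal and 21 with only the compared groups. On log2 of FPKM plus 1 the split was 6 and 5.

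The comparison of hIAPP-hCAST with hCAST asked for the human IAPP difference on the calpastatin background and shares no library with hIAPP against WT. Macrophage genes rose in 12 of 22, 0 fell and 10 did not pass, and 18 rose when adjusted over the list alone (median 0.91, camera adjusted p = 4.63e-25; adjusted p = 0.0475 with an estimated correlation). Lyz2 had 65.6 ± 29.7 CPM in hIAPP-hCAST and 12.2 ± 0.481 in hCAST (SD, n = 3; log2 fold change 2.43 ± 0.264, adjusted p = 0.00130), and Cd84, a receptor of immune cells, rose by 2.14 ± 0.240. With only the compared groups neither Lyz2 (0.0977) nor Cd84 (0.0582) passed. Lymphocyte markers rose in 2 of 5 tested, 0 fell and 3 did not pass, and 3 rose when adjusted over the list alone (median 1.13, camera adjusted p = 0.000395; adjusted p = 0.0475 with an estimated correlation). Endothelial genes gave 0 of 13 passing, with 1 lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.000395; adjusted p = 0.410 with an estimated correlation), and the camera adjusted p was 0.242 without hIAPP-hCAST 3. Sema5a had 570 ± 43.6 CPM against 11.5 ± 1.29 (log2 fold change 5.63 ± 0.136, adjusted p = 5.46e-14), Snhg18 101 ± 12.7 against 6.31 ± 0.416 and Osbpl1a 29.9 ± 4.43 against 4.14 ± 0.207. Matrix genes gave 0 of 22 passing, with 2 rising when adjusted over the list alone (median -0.02, mean 0.08, camera adjusted p = 0.657), and the camera adjusted p was 2.86e-06 without hIAPP-hCAST 3 and 0.0213 without hCAST 3. Beta-cell genes gave 1 falling, 0 rising and 29 not passing, and 5 falling when adjusted over the list alone (median -0.15, camera adjusted p = 1.86e-06; adjusted p = 0.352 with an estimated correlation). Ucn3 had 230 ± 17.4 CPM against 375 ± 31.0 (adjusted p = 0.0130), which did not pass without hIAPP-hCAST 2 (0.0531), hCAST 1 (0.0760) or hCAST 2 (0.0792). Ins2 (-0.40, adjusted p = 0.134), Ins1 (0.432), Iapp, Cast, Gcg, Sst and Ppy did not pass. Cd74 and H2-Aa, antigen-presentation genes, had 30.1 ± 3.06 against 75.4 ± 3.46 and 16.9 ± 2.70 against 44.4 ± 3.55 CPM, with an adjusted p of 0.0178 for each. Cd74 lost the call without hIAPP-hCAST 1 (0.0532), hIAPP-hCAST 2 (0.0549), hCAST 1 (0.0825) or hCAST 2 (0.0792), and H2-Aa without hIAPP-hCAST 2 (0.0606), hCAST 1 (0.0844) or hCAST 2 (0.0666). The acinar median was 0.24 with a camera direction of lower (adjusted p = 0.209), and without hIAPP-hCAST 3 it was 0.77 (adjusted p = 1.74e-05) and without hIAPP-hCAST 2 -0.69 (3.15e-08). The calls were 80 higher and 36 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), 116 in all, against 9 with only the compared groups, 53 without the 3 ribosomal-rich libraries, 36 without hCAST 2, 48 without hCAST 1 and 356 without hIAPP-hCAST 3. Of 22 called genes chosen for naming, 13 lost the call in at least 1 removal and 17 with only the compared groups. On log2 of FPKM plus 1 the split was 15 and 4.

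The interaction asked whether the human IAPP difference varies with calpastatin. No gene passed (0 by the edgeR quasi-likelihood test with Benjamini-Hochberg), 1346 had an unadjusted p under 0.05, DESeq2 called 47, among them Sdc1 and Loxl1, and voom with sample weights 2. The smallest p values were those of Sdc1, a syndecan (-1.21 ± 0.195, adjusted p = 0.158), and Loxl1 (-1.57 ± 0.268, adjusted p = 0.158). Loxl1 had an adjusted p of 0.00971 and Sdc1 of 0.0225 without hIAPP-hCAST 2, and Sdc1 of 0.0499 without WT 3, and the count was 5 without hIAPP-hCAST 2, 4 without hIAPP-hCAST 1, 2 without WT 3 and 1 without hIAPP-hCAST 3. Matrix genes gave 0 of 22 passing, with 15 lower when adjusted over the list alone (median -1.34, camera adjusted p = 1.17e-17; adjusted p = 0.298 with an estimated correlation). Macrophage genes gave 0 of 22, with 9 lower when adjusted over the list alone (median -0.78, camera adjusted p = 5.19e-11; adjusted p = 0.298 with an estimated correlation). Over the 1833 genes called in hIAPP against WT, the slope of log2 fold changes on the hCAST background against those on the WT background was 0.397, and 1675 of them (91.4%) had the same direction, of which 88 were called in both. Draws with equal effects on both backgrounds gave slopes of 0.651 to 0.742. These draws share 1 dispersion per gene and do not model extra spread in WT or in hIAPP-hCAST 3. They called 724 to 880 genes in hIAPP against WT and 1022 to 1200 in hIAPP-hCAST against hCAST, unlike the 1833 and 116 observed. Over the 116 genes the slope was 0.731, with 0.935 to 1.07 in the draws. The reverse slope over the same genes was 1.09, with 0.740 to 0.829 in the draws.

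**Figure D4:**
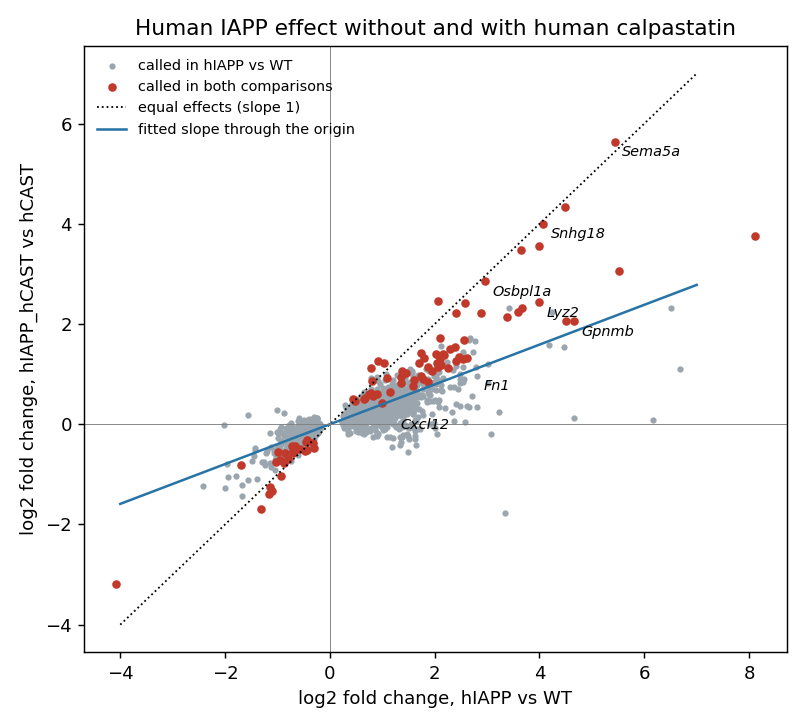
Log2 fold change of hIAPP-hCAST against hCAST (vertical) and of hIAPP against WT (horizontal) for the 1833 genes called in hIAPP against WT, with genes called in both in red, a dotted line of slope 1 and the fitted slope in blue. The fitted slope is 0.397 and 88 genes are called in both.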

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

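All tests in this part were chosen after the result was seen, except the macrophage comparison with hCAST and the splits of the 6 pairwise comparisons. The slope of 0.397 drew attention because the human IAPP difference was smaller on the hCAST background than on the WT background, below all draws with equal effects (0.651 to 0.742), while no gene passed the interaction test; over the 116 genes called on the hCAST background it was 0.731 (0.935 to 1.07 in the draws). The lower number of calls on the hCAST background was weighed as well. Against ribosomal reads in the WT libraries as the whole cause of it, 1112 genes were called with hCAST in place of WT, against 116 in hIAPP-hCAST and hCAST. These counts do not show whether the WT libraries lower the slope. A swap of hIAPP-hCAST 3 with an hCAST library is argued against by Sema5a at 613 CPM in it, where hCAST libraries had 10.0 to 12.5. That library alone cannot be told apart as a cause. Without it 356 genes were called, while hIAPP against hCAST with 1 hIAPP library left out gave 672, 563 and 600. The latter fits kept hIAPP-hCAST 3 in the shared spread, so their counts cannot be compared directly with the 356. Leaving out hIAPP-hCAST 3 moved even hIAPP against WT from 1833 to 2418. The slope without hIAPP-hCAST 3 was 0.459, still below the draws, whose limits are given next. Smaller effects on the hCAST background cannot be told apart from greater spread either, because the equal-effect draws do not model the spread of WT or of hIAPP-hCAST 3 and called 724 to 880 genes in hIAPP against WT and 1022 to 1200 in hIAPP-hCAST against hCAST, where the data gave 1833 and 116. The reverse slope over the 116 genes was 1.09, above the 0.740 to 0.829 of the draws, which have the same limits.

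Sema5a and Snhg18 were higher in all 6 libraries with human IAPP, and Tram1l1 and 1700006A11Rik in all 6 with human CAST. Reads shared by overlapping genes are argued against for Sema5a and Snhg18, which share 0 exon bases and lie 147 bases apart on opposite strands, though the strand setting of the counting is not given. A difference at 1 locus carried with the hIAPP line may be involved, since 4 other genes within 5 Mb (Ankrd33b, Cmbl, Cpq and Sdc2) were called in both comparisons, as many as in 2.13% of 10000 random windows, though all 4 were lower (-0.72, -0.93, -0.70 and -0.30 in hIAPP against WT), opposite to Sema5a, and the test asked for no direction. Snord123 and Snhg18 were left out of that count after it was seen. A difference at 1 locus carried with the hCAST line may likewise be involved for Tram1l1 and 1700006A11Rik, which lie 76245 bases apart, and an effect of the transgene product itself was not tested. H2-Ea-ps had 52.3, 48.8 and 47.2 CPM in hCAST and 98.7, 52.4 and 117 in hIAPP-hCAST, and at most 1.18 in the other libraries. It lies on chromosome 17, while Tram1l1 and 1700006A11Rik lie on chromosome 3. Of 189 tested genes within 5 Mb of H2-Ea-ps, 0 others were called in hCAST against WT. A difference at a further locus carried with the hCAST line may be involved, which was not tested.

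Macrophage genes were higher in hIAPP than in WT. A lower share of beta cells would raise the markers of all other cell types alike, but the rises of 7 other non-beta lists differed. They ran from -0.01 to 1.32, and the macrophage list rose by 1.61 more than their median on the log2 scale. The alpha-cell list lay at that median, and the SE of the difference from it was 0.237. The excess was 0.68 ± 0.208 over lymphocyte, 0.72 ± 0.266 over stellate and 0.78 ± 0.814 over acinar markers. The Schwann and glial list, which rose by 0.66 ± 0.292, was not among the 7. Ribosomal reads in WT are argued against by a difference of 1.59 ± 0.250 against hCAST, which holds few of them. More macrophages in the islets and more expression per macrophage stay open, as neither was tested.

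With 10 splits of 6 libraries, a share under 0.05 cannot be reached. The real split was the 1 with as many calls in hIAPP against WT (1833, highest other 0), rIAPP against WT (3599, highest other 0), hIAPP against rIAPP (2009, highest other 0), hCAST against WT (3, highest other 0) and hIAPP-hCAST against hIAPP (72, highest other 1). The other splits mix the compared groups on each side without removing their difference, which widens the spread within a side. Their low counts therefore do not measure what chance would give. For hIAPP-hCAST against hCAST, 2 of 10 splits gave as many as the real 116. Exchanging hIAPP-hCAST 3 with hCAST 3 gave 316, which points to a structure of the samples. That split also separates the libraries by acinar share. The share was at least 8.18% in hIAPP-hCAST 1 and 2 and hCAST 3. It was at most 5.79% in hIAPP-hCAST 3 and hCAST 1 and 2. With the acinar covariate the real split gave 330 calls. Whether acinar content accounts for the 316 calls was not tested. For the interaction, with 0 genes, all 100 of 100 splits drawn give as many by construction, which says nothing about chance. The highest other count was 260. These draws shuffle all 12 libraries without removing the group differences, so the 260 does not show a further structure of the samples.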

How the results depend on the processing

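Leaving out the 3 ribosomal-rich libraries or the 3 ribosomal-rich genes, hCAST in place of WT, voom with sample weights, rIAPP against hCAST and leaving out libraries of groups not compared were chosen after seeing the data, and the other settings before. Of 244 gene results chosen for naming, called or not (187 were called), 81 kept their direction and side of the threshold in all settings run for them (libraries of groups not compared were left out for counts alone), as did 9 of 62 lists (50 called), where the estimated correlation alone ended 47 calls. DESeq2 size factors, TMM without hormone and acinar genes, and leaving out the ribosomal-rich genes kept all 9 counts within 1.5 times. No paired analysis was run, because the numbers in the titles are not shared between groups and replicate numbers were given in accession order. Depth limits WT 2 most, with 1667190 counts outside the ribosomal-rich genes. The cause was not tested.

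For hIAPP against WT, 1833 calls became 383 without the 3 libraries, 1112 with hCAST in place of WT, 12559 on FPKM plus 1, 12009 on FPKM plus 0.1, and 995 to 1414 with 1 replicate of the compared groups left out, as in all ranges here unless stated. The 3599 of rIAPP against WT became 1525 without the 3 libraries, 820 and 719 on FPKM plus 1 and plus 0.1, and 2623 to 3335 with 1 replicate left out. The 2009 of hIAPP against rIAPP became 316 and 101 on FPKM, 3476 with voom, and 1302 to 1728. For hCAST against WT, 3 became 28 with DESeq2, 13135 and 13310 on FPKM, and 3 to 4. The 72 of hIAPP-hCAST against hIAPP became 116 with no filter, 124 with the acinar covariate, 30 without the 3 libraries, 2 with only the compared groups, 283 with DESeq2, 11 and 3 on FPKM, 114 with voom, and 18 to 175. The 116 of hIAPP-hCAST against hCAST became 330 with the covariate, 53 without the 3 libraries, 9 with only the compared groups, 258 with DESeq2, 19 and 13 on FPKM, 313 with voom, and 36 to 356. The interaction's 0 became 47 with DESeq2, 50 and 11 on FPKM, 2 with voom, and 0 to 5. The slope became 0.432 with the covariate, 0.477 with voom, 0.731 over genes called in hIAPP-hCAST against hCAST, and 0.327 to 0.467. The overlap of 1134 became 210 without the 3 libraries and 612 to 934. Leaving out 1 library of a group not compared gave 1489 to 2418 in hIAPP against WT, 3326 to 4219 in rIAPP against WT, 1825 to 2500 in hIAPP against rIAPP, 42 to 81 in hIAPP-hCAST against hIAPP (43, 42 and 45 without rIAPP 1, 2 and 3, and 44 without hCAST 2) and 78 to 126 in hIAPP-hCAST against hCAST, with the first 3 highest without hIAPP-hCAST 3.

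The acinar list reversed with its own covariate, which removes it by construction, to -0.0346 in hIAPP and -0.0774 in rIAPP against WT, 0.00630 in hIAPP-hCAST against hIAPP and 0.0419 in the interaction. With 1 replicate left out it ran from -1.18 to 0.23 against hIAPP and from -0.69 to 0.77 against hCAST, the highest without hIAPP-hCAST 3. On FPKM plus 1 and plus 0.1, whose totals include ribosomal reads, reversals in hIAPP against WT were Cast 1.39 and 1.83, Ins1 1.46 and 1.46, Ins2 1.28 and 1.28, Nnat 0.25 and 0.29, Trpm5 0.16 and 0.24, Ucn3 1.04 and 1.05, Ero1lb 1.16 and 1.18, Chga 1.41 and 1.41, Slc7a2 1.19 and 1.28, and on plus 0.1 alone Slc14a2 0.10, Fcgbp 0.0241 and Adam32 0.19. In rIAPP against WT they were Ins2 0.12 and 0.12, Sst 1.14 and 1.14, Loxl2 0.19 and 0.44, Scg2 0.41 and 0.41, Pcsk2 0.57 and 0.57, and Mki67 0.0218 and 0.18. In hIAPP against rIAPP they were Emcn 0.0668 and 0.0733, and Eng 0.0132 on plus 0.1, and in hCAST against WT on plus 0.1 Sst 1.86 and Ppy 1.99.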

Other observations

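The lists in this part were picked from the 27 after their results were known, and no hypothesis test was added. Genes that beta cells normally keep low rose in hIAPP against WT in 7 of 20, with 0 falling and 13 not passing, and 10 rose when adjusted over the list alone (median 0.61, camera adjusted p = 2.37e-05; adjusted p = 0.311 with an estimated correlation), with Cxcl12, a chemokine, at 1.22 ± 0.162. Islets were measured in bulk, so the cells in which these genes rose were not resolved. The mean log2 CPM of this list exceeded WT by 0.81 ± 0.217 SE, and that of the matrix list by 1.28 ± 0.250. Immediate-early genes rose in 7 of 13, with 0 falling and 6 not passing, and 10 rose when adjusted over the list alone (median 1.03, camera adjusted p = 4.86e-06; adjusted p = 0.298 with an estimated correlation). The mean log2 CPM of that list exceeded WT by 1.15 ± 0.294 SE in hIAPP, 0.83 ± 0.294 in rIAPP and 0.37 ± 0.294 in hCAST. ER stress genes gave 7 rising, 1 falling and 24 not passing of 32, with 11 rising and 1 falling when adjusted over the list alone (median 0.24, camera adjusted p = 0.00780; adjusted p = 0.255 with an estimated correlation), with Ppp1r15a, a phosphatase subunit of the stress response, at 0.81 ± 0.141. Genes of the NF-kB response gave 6 rising, 0 falling and 14 not passing of 20, with 7 rising when adjusted over the list alone (median 0.65, camera adjusted p = 0.0541), with Tnfrsf1b, a receptor for TNF, at 1.4 ± 0.239, which did not pass without the 3 ribosomal-rich libraries (adjusted p = 0.0616). That list's camera adjusted p was 0.0360 without hIAPP 1, 0.0132 without hIAPP 2 and 0.00152 without WT 2. Its mean log2 CPM exceeded WT by 0.53 ± 0.1315 SE in hIAPP and 0.31 ± 0.1315 in rIAPP.

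In rIAPP against WT, the list of genes that beta cells keep low gave 7 rising, 0 falling and 13 not passing of 20, with the same count adjusted over the list alone (median 0.52, camera adjusted p = 0.000962; adjusted p = 0.524 with an estimated correlation), with Cxcl12 at 1.21 ± 0.164. Here too the cells in which these genes rose were not resolved. ER stress genes rose in 5 of 32, with 0 falling and 27 not passing, and 5 when adjusted over the list alone (median 0.22, camera adjusted p = 0.0106; adjusted p = 0.486 with an estimated correlation), with Eif2ak3, a kinase of the unfolded protein response, at 0.68 ± 0.119 and Sesn2, a stress-induced sestrin, at 0.75 ± 0.144. Without the 3 ribosomal-rich libraries neither Eif2ak3 (0.0743) nor Sesn2 (0.0682) passed, and the ER stress list had a camera adjusted p of 0.0655.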
